A study of Mus musculus with 8 samples.

How the data were processed

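RNA was measured on single-colour microarrays in epithelial cells carrying the surface protein Epcam, taken from mouse lungs at embryonic stage E18.5. Per the labels' protocols, the lungs were dissociated mechanically and enzymatically, the cells were selected with Epcam magnetic beads, and total RNA was labelled with biotin. The 8 arrays fall into 4 control and 4 knockout arrays, and the labels call each a biological replicate. Per the series' design text, the knockout animals lack the Hippo kinases Mst1 and Mst2 (gene symbols Stk4 and Stk3) wherever Cre recombinase driven from the Shh locus had been active, which covers the epithelial progenitors of the developing lung.

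The table of values deposited by the authors holds log2 expression for 35556 probe sets in each of the 8 arrays. That the values are on a log2 scale was read from their range and is not stated in the labels. The normalization method and the software behind it are not given in the sources used here. The array medians were 7.25, 7.21, 7.29 and 7.25 in control replicates 1 to 4 and 7.25, 7.24, 7.24 and 7.30 in knockout replicates 1 to 4. At every rank, the value of each array differed by at most 0.17 from the mean of the 8 arrays at that rank, so the arrays had already been brought to nearly the same distribution, and no further scaling was applied. Such scaling would hide a change in total RNA per cell, so each difference is relative to the array as a whole. No gene had been centred. The arrays carry no count of molecules, and their number limits the precision. Gene symbols came from the array platform's annotation in GEO, in which 21789 probe sets have 1 symbol, 1621 have several and 12146 have none given. Of the probe sets with 1 symbol, 21698 matched by gene number to the RefSeq gene table of assembly GRCm38.p6, and the match changed 0 symbols. That table also gave which genes lie next to each other. No coordinates are printed because the sources used here name no genome build for the probe sets.

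A gene was taken as a symbol that is the only symbol of a probe set. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 19938 genes. Knockout and control were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with default settings and no covariate. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all 19938 genes, with a threshold of 0.05. Errors of differences are limma's moderated standard errors, and errors of group means are standard deviations over the 4 arrays of a group. For Stk4 an exact permutation test over all 70 assignments of the arrays was run as well.

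The 23 gene lists were written down by hand, and 22 of them were tested as sets. The 8 primary lists are YAP/TAZ target genes, mitosis genes, DNA replication genes, markers of alveolar type 1 cells, alveolar type 2 cells, club and secretory cells and ciliated cells, and markers of basal cells and stratified epithelium. The secondary lists are Hippo pathway components, surfactant lipid and sterol synthesis genes, distal tip progenitor genes, neuroendocrine markers, Notch pathway genes, Wnt pathway genes, p53 targets with cell cycle inhibitors, general epithelial genes, mesenchymal, endothelial, leukocyte, erythroid and mesothelial markers, and immediate early genes that respond to tissue dissociation. A list of sex-linked genes was used only to compare the arrays. Each tested list was compared with all other genes by camera with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 22 lists. Camera with a correlation estimated from the arrays was run beside it, as was fry, which tests whether a list's own members move on balance in a single direction without comparing them with other genes. Members passing the gene test were counted after adjustment over all genes and again adjusted over the list alone. Only list members with a probe set of their own single symbol in the table used here were measured, and the others, Ddx3y among them, were not analysed here and are not reported. The deleted gene Stk3 was not analysed here either.

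The rule for naming genes took Stk3, Stk4, Yap1 and Wwtr1, then the 6 largest rises and the 6 largest falls among genes that passed the test and whose 4 knockout values all lay above or all below the 4 control values. It also took the 3 members with the smallest p of each primary list, the 1 such member of each secondary list, and Xist and Ddx3y. Any other gene named was chosen after its values were seen. The groups, the tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined, apart from 3 alternatives that were added later. Those 3 leave out knockout replicates 1 and 4 together, add the mean of the mesenchymal markers per array as a covariate, or add the level of Xist as a covariate.

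The alternatives fixed in advance were a block for the replicate number, centring each array on its median, quantile normalization between arrays, a filter keeping the genes above the median level, the mean of all probe sets of a gene, every probe set tested on its own, eBayes with trend and robust estimation, array weights, a minimum change of 1.5-fold, limma's treat test against a 1.2-fold change, leaving out each of the 8 arrays in turn, camera with an estimated correlation, and fry. The gene and list tests were tested on simulated data in which unchanged values for the 19938 genes of the comparison of knockout with control were drawn with each gene's own spread. Of 100 simulated genes changed 1.5-fold, 88% were called, as were 98% of 100 genes changed 2-fold, while 7.37% of all calls were unchanged genes. A single simulated list shifted by 0.5 was called with the right direction, and 0 of the other lists were called among the 22 lists tested. The simulated genes were drawn independently of each other, so this run cannot show how often lists of correlated genes are called falsely. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.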

Results

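Expression was measured in epithelial cells isolated from mouse lungs at embryonic stage E18.5, shortly before birth, when the distal lung epithelium is dividing into the flat type 1 cells of gas exchange and the surfactant-producing type 2 cells. There were 4 control arrays and 4 arrays of animals in which both Hippo kinases Mst1 and Mst2 had been deleted in the lung epithelium. These kinases act through Lats1 and Lats2 to restrain the transcriptional coactivators Yap and Taz. The comparison asks which transcripts change in the epithelium when this restraint is removed. Values are log2 expression, each difference is knockout minus control with its standard error (SE) and n = 4 arrays per group, and the number of arrays limits the precision. The p-values of single genes set the group difference against the spread between arrays within the groups, moderated over all genes. Whether each array stands for 1 independent animal is not known.

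Stk4, which encodes Mst1, was measured by probe set 10478447. Its level was 9.66 ± 0.12 (SD, n = 4) in control and 9.36 ± 0.10 in knockout arrays, a fall of 1.23-fold (log2 difference −0.30, SE 0.076, adjusted p = 0.0188). The control values were 9.59, 9.84, 9.59 and 9.62 and the knockout values 9.45, 9.44, 9.31 and 9.24. All knockout values lay below all control values, and the exact permutation test gave p = 0.0286, the smallest p that 4 against 4 arrays can give. Leaving out knockout replicate 3 ended the call (−0.28, adjusted p = 0.0592), and the adjusted p was 0.178 with the mesenchymal marker mean as a covariate, an alternative added after the data were seen. The probe set may lie outside the deleted exons, so its value does not check the deletion. Stk3, which encodes Mst2, was not analysed here. The transcripts of the effectors did not pass the test: Yap1 differed by 0.09 (SE 0.058, adjusted p = 0.360) and Wwtr1, which encodes Taz, by 0.18 (SE 0.067, adjusted p = 0.0931).

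Of 19938 genes, 3746 (18.8%) changed in limma's test, 1715 of them higher and 2031 lower in knockout cells. The median size of the change was 0.41 on the log2 scale, and 79 genes were higher and 265 lower by at least 2-fold. In 3433 of the changed genes the values of the groups did not overlap. Among all genes 22.1% had no overlap, where chance gives 2.86%. The largest rises were those of Psca, a surface antigen anchored in the membrane by glycolipid (9.60-fold, log2 difference 3.26, SE 0.35), Igfbp2, a binding protein of insulin-like growth factors (5.11-fold, 2.35, SE 0.065), and Krt4, a keratin of stratified mucosal epithelia (4.81-fold, 2.27, SE 0.14). Lox, the lysyl oxidase that crosslinks collagen and elastin, rose 4.39-fold (SE 0.15 on the log2 scale), the transcript AU018091 rose 4.17-fold (SE 0.10), and Ddah1, which degrades inhibitors of nitric oxide synthase, rose 4.01-fold (SE 0.15).

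The largest falls were those of secreted proteins and enzymes. Pon1, a paraoxonase carried on high-density lipoprotein, went from 11.04 ± 0.34 (SD, n = 4) in control to 6.40 ± 1.38 in knockout arrays (log2 difference −4.64, SE 0.54). In knockout replicates 2 to 4 Pon1 was at 5.56 to 5.93. In arrays without them, Xist read 5.85 to 6.33 and Eif2s3y 4.16 to 4.40, so background differs between probe sets. Whether Pon1 was at its own background there is not known, and the size of its fall may be a lower bound. Retnla, a secreted resistin-like protein, went from 12.31 ± 0.20 to 8.32 ± 1.77 (−3.98, SE 0.67, adjusted p = 0.00189). Gdpd2, a glycerophosphodiester phosphodiesterase, changed by −3.54 (SE 0.30), the complement components C6 and Hc by −3.19 (SE 0.26) and −3.14 (SE 0.38), and the chitinase-like Chil1 by −2.87 (SE 0.38). In Pon1, Gdpd2 and C6 the value of knockout replicate 1 (8.46, 8.50 and 7.63) lay between the control arrays and the other knockout arrays. C6 in the other knockout arrays (6.19 to 6.41) and Krt4 in control (5.91 ± 0.15) were also low. Whether they were at background is not known either, so the sizes of their changes may be lower bounds too. The adjusted p of these 12 genes lay between 3.95e-08 (Igfbp2) and 0.00189 (Retnla).

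**Figure D1:**
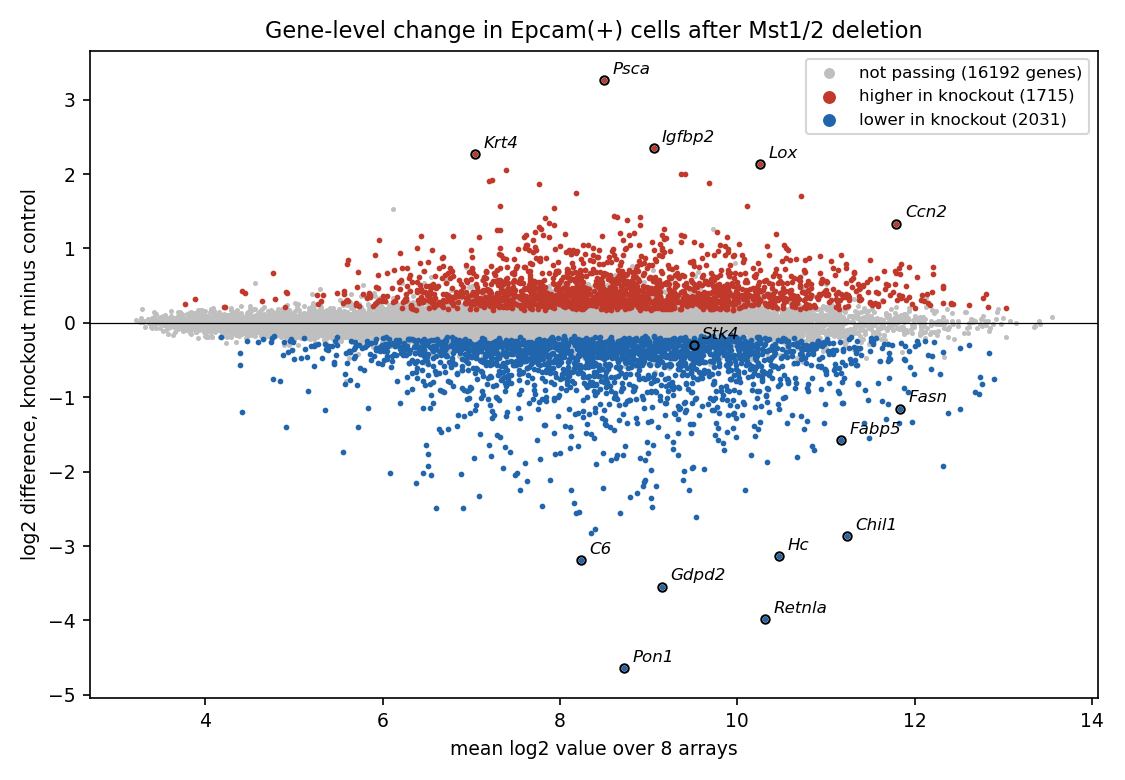
Each point is a gene, with its mean log2 value over the 8 arrays on the horizontal axis and its log2 difference, knockout minus control, on the vertical axis. Red points are the 1715 genes higher and blue points the 2031 genes lower in knockout cells at an adjusted p under 0.05, and the labelled falls reach further from 0 (Pon1, −4.64) than the labelled rises (Psca, 3.26).

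YAP/TAZ target genes rose as a list. Of 22 measured members 13 rose, 2 fell and 7 did not pass, and adjusted over the list alone 14 rose and 2 fell. Ccn2, a matricellular protein used widely as a readout of Yap activity, rose 2.52-fold (1.33, SE 0.078, adjusted p = 7.12e-06). Nt5e, the ectonucleotidase CD73, rose 2.68-fold (1.42, SE 0.13) and Myof, a ferlin of the plasma membrane, 1.60-fold (0.68, SE 0.058). The members that fell were Gadd45a, a growth arrest gene (−0.72, SE 0.078), and Nuak2, a stress-responsive kinase (−0.27, SE 0.072), both named after their values were seen. The list median was 0.40, with camera adjusted p = 1.30e-06 but adjusted p = 0.147 with an estimated correlation. The mesenchymal marker mean was higher in the knockout arrays as well, at 8.45 ± 0.26 (SD, n = 4) against 8.16 ± 0.17. With that mean as a covariate 8 members of the YAP/TAZ list rose and 2 fell, and the list median was 0.35 (camera adjusted p = 4.41e-05).

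Hippo pathway components also rose as a list. Of 23 measured members 11 rose, 1 fell and 11 did not pass, and adjusted over the list alone 15 rose and 1 fell. Ajuba, a LIM protein that binds Lats kinases, rose 2.28-fold (1.19, SE 0.082, adjusted p = 1.02e-05). Other members that rose, named after their values were seen, were the Yap-binding Amot (0.74, SE 0.071), the DNA-binding partner Tead1 (0.56, SE 0.068) and the kinase Lats2 (0.66, SE 0.064). Vgll4, which competes with Yap for Tead, fell (−0.35, SE 0.098, adjusted p = 0.0306), a call that ended without any 1 of control replicates 1 and 2 and knockout replicates 2 and 4, without knockout replicates 1 and 4 together, and with the mesenchymal covariate. Lats2, Ptpn14 and Amotl2 belong to this list and to the YAP/TAZ list. Its median was 0.24 (camera adjusted p = 3.28e-08, adjusted p = 0.147 with an estimated correlation).

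Cell division genes were higher in the knockout cells. All 25 measured mitosis genes rose, over all genes and adjusted over the list alone, by log2 differences from 0.35 to 1.05. Mki67, the proliferation marker Ki-67, rose 1.77-fold (0.82, SE 0.067, adjusted p = 2.22e-05), Cenpe, a kinesin of the kinetochore, 1.91-fold (0.93, SE 0.077), and Kif20a, a kinesin of cytokinesis, 1.61-fold (0.69, SE 0.071). Of 25 DNA replication genes 16 rose, 0 fell and 9 did not pass, and adjusted over the list alone 17 rose and 0 fell. Among them E2f1, a transcription factor of S phase entry, rose 1.43-fold (0.52, SE 0.068), and the helicase subunits Mcm6 and Mcm3 rose 1.35-fold (0.43, SE 0.063) and 1.34-fold (0.43, SE 0.066). Pcna, the sliding clamp, was named after its value was seen and did not pass (−0.13, SE 0.061, adjusted p = 0.172). The list medians were 0.63 for mitosis (camera adjusted p = 8.49e-22) and 0.32 for DNA replication (camera adjusted p = 8.63e-09), each with adjusted p = 0.147 with an estimated correlation. Among genes above the median level 14 DNA replication genes are left, of which 9 rose.

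Markers of the alveolar cell types moved in opposite directions. Of 20 type 1 markers 16 rose, 0 fell and 4 did not pass, and adjusted over the list alone 17 rose and 0 fell. Besides Igfbp2, the guidance molecule Sema3e rose 2.06-fold (1.04, SE 0.10, adjusted p = 6.92e-05) and Scnn1g, the gamma subunit of the epithelial sodium channel, 1.67-fold (0.74, SE 0.079). Some well known type 1 markers, named after their values were seen, rose less, Hopx by 0.59 (SE 0.066), Pdpn by 0.52 (SE 0.080), Aqp5 by 0.31 (SE 0.090) and Ager by 0.24 (SE 0.062). The members that did not pass, also named after their values were seen, were Emp2 (0.19, SE 0.060, adjusted p = 0.0548), Timp3 (0.15, SE 0.079, adjusted p = 0.238), Cav1 (0.14, SE 0.083, adjusted p = 0.291) and Cldn18 (−0.06, SE 0.087, adjusted p = 0.718). The type 1 list had a median of 0.40 (camera adjusted p = 7.31e-14, adjusted p = 0.147 with an estimated correlation).

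Of 22 type 2 markers 20 fell, 0 rose and 2 did not pass, with the same counts adjusted over the list alone. S100g, a calcium-binding protein, changed by −2.29 (SE 0.18, adjusted p = 1.92e-05), the fatty acid-binding protein Fabp5 by −1.58 (SE 0.12) and the phosphatase inhibitor Ppp1r14c by −1.22 (SE 0.094). Among members named after their values were seen, the lamellar body transporter Abca3 fell by 1.05 (SE 0.090), the surfactant protein gene Sftpa1 by 1.22 (SE 0.20) and Sftpb by 0.73 (SE 0.075). The members that did not pass were Ctsh (−0.22, SE 0.10, adjusted p = 0.202) and Sftpc (−0.05, SE 0.051, adjusted p = 0.553), the latter among the brightest genes of the array. Sftpc averaged 13.38 in control and 13.32 in knockout arrays, near the highest values of the arrays (13.69 to 13.95). Whether a fall could still show that near the top of the range was not tested. The type 2 list had a median of −1.13 (camera adjusted p = 4.14e-19, adjusted p = 0.147 with an estimated correlation). The mean of the type 2 markers was 11.16 in knockout replicate 1 and 10.76, 10.83 and 10.40 in knockout replicates 2 to 4, against 12.07 ± 0.11 (SD, n = 4) in control arrays.

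Genes of surfactant lipid and sterol synthesis fell with the type 2 markers, and Fabp5, Abca3 and Lpcat1 belong to both lists. Of 22 measured members 16 fell, 0 rose and 6 did not pass, and adjusted over the list alone 16 fell and 2 rose. Fasn, the fatty acid synthase, fell 2.22-fold (−1.15, SE 0.079, adjusted p = 9.72e-06). Gpam (−1.43, SE 0.11), Scd1 (−1.16, SE 0.14) and Srebf1 (−0.71, SE 0.090), genes of glycerolipid assembly, fatty acid desaturation and the transcriptional control of lipid synthesis, were named after their values were seen. The cholesterol synthesis genes Sqle (0.17, SE 0.065, adjusted p = 0.100) and Hmgcs1 (−0.07, SE 0.063, adjusted p = 0.574) did not pass. Over the lipid list the median was −0.58 (camera adjusted p = 2.77e-09, adjusted p = 0.147 with an estimated correlation).

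**Figure D2:**
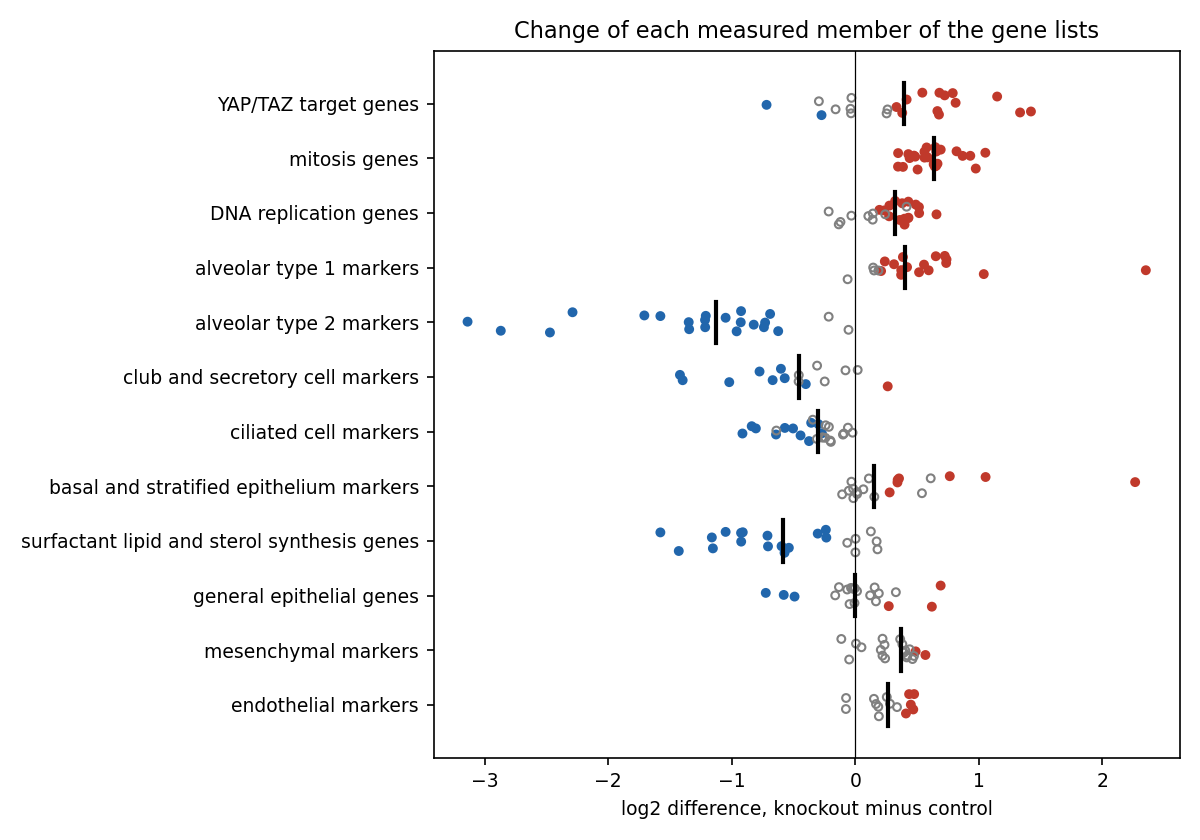
Each point is a measured member of a gene list, placed by its log2 difference, knockout minus control, and the black bar is the list median. Red members rose, blue members fell and open grey members did not pass at an adjusted p under 0.05, with 20 of 22 type 2 markers lower and 25 of 25 mitosis genes higher.

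In the conducting airway lists, club and secretory markers fell. Of 15 members 8 fell, 1 rose and 6 did not pass, and adjusted over the list alone 12 fell and 1 rose. Bpifb1, an airway secretory protein, fell 2.68-fold (−1.42, SE 0.20, adjusted p = 6.29e-04), Hp, haptoglobin, 1.52-fold (−0.60, SE 0.098) and Aldh1a7, an aldehyde dehydrogenase, 1.71-fold (−0.78, SE 0.13). Aldh1a7 closely resembles Aldh1a1, so its value is uncertain. The member that rose was Cyp4b1, a cytochrome P450 (0.26, SE 0.072, a call that ended without any 1 of control replicates 1 and 3 and knockout replicates 1 and 4, without the latter 2 together, and with the mesenchymal covariate), and the classical marker Scgb1a1 did not pass (−0.46, SE 0.18, adjusted p = 0.114), both named after their values were seen. Cyp2f2, another bright member (12.48 in control), did not pass either (0.02, SE 0.10, adjusted p = 0.933) and was also named after its value was seen. For the club and secretory list the median was −0.46 (camera adjusted p = 9.01e-05, adjusted p = 0.149 with an estimated correlation).

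Ciliated cell markers fell as a list. Of 25 members 11 fell, 0 rose and 14 did not pass, and adjusted over the list alone 13 fell and 0 rose, while all 25 differences were negative. Ccno, a cyclin-like gene needed for centriole amplification, fell 1.88-fold (−0.91, SE 0.083, adjusted p = 4.10e-05), Lrrc23, a radial spoke protein, 1.75-fold (−0.81, SE 0.12), and Rfx3, a transcription factor of ciliogenesis, 1.30-fold (−0.37, SE 0.057). For the ciliated list the median was −0.30 (camera adjusted p = 8.23e-07, adjusted p = 0.295 with an estimated correlation). The count of fallen members depended on single arrays, with 7, 5 and 5 without control replicates 2, 3 and 4, 6 without knockout replicate 1, 6 without knockout replicate 3 and 17 without knockout replicate 4, and it was 7 with the mesenchymal marker mean as a covariate.

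Markers of basal cells and stratified epithelium rose as a list. Of 19 measured members 7 rose, 0 fell and 12 did not pass, and adjusted over the list alone 8 rose and 0 fell. Besides Krt4, its partner keratin Krt13 rose 1.70-fold (0.77, SE 0.11, adjusted p = 8.23e-04) and Krt14, a keratin of basal layers, 1.28-fold (0.35, SE 0.055). Krt15, another basal keratin, rose 2.08-fold (1.05, SE 0.18, adjusted p = 0.00192) and Itgb4, an integrin of hemidesmosomes, rose by 0.28 (SE 0.073, adjusted p = 0.0217), while the basal cell genes Krt5 (0.11, SE 0.085, adjusted p = 0.456) and Trp63 (0.01, SE 0.054, adjusted p = 0.903) did not pass. These 4 genes were named after their values were seen. Across the basal list the median was 0.15 (camera adjusted p = 1.61e-04, adjusted p = 0.242 with an estimated correlation). It was 0.10 without control replicate 2, and among genes above the median level, where 7 members are left, 4 rose and the median was 0.34.

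**Figure D3:**
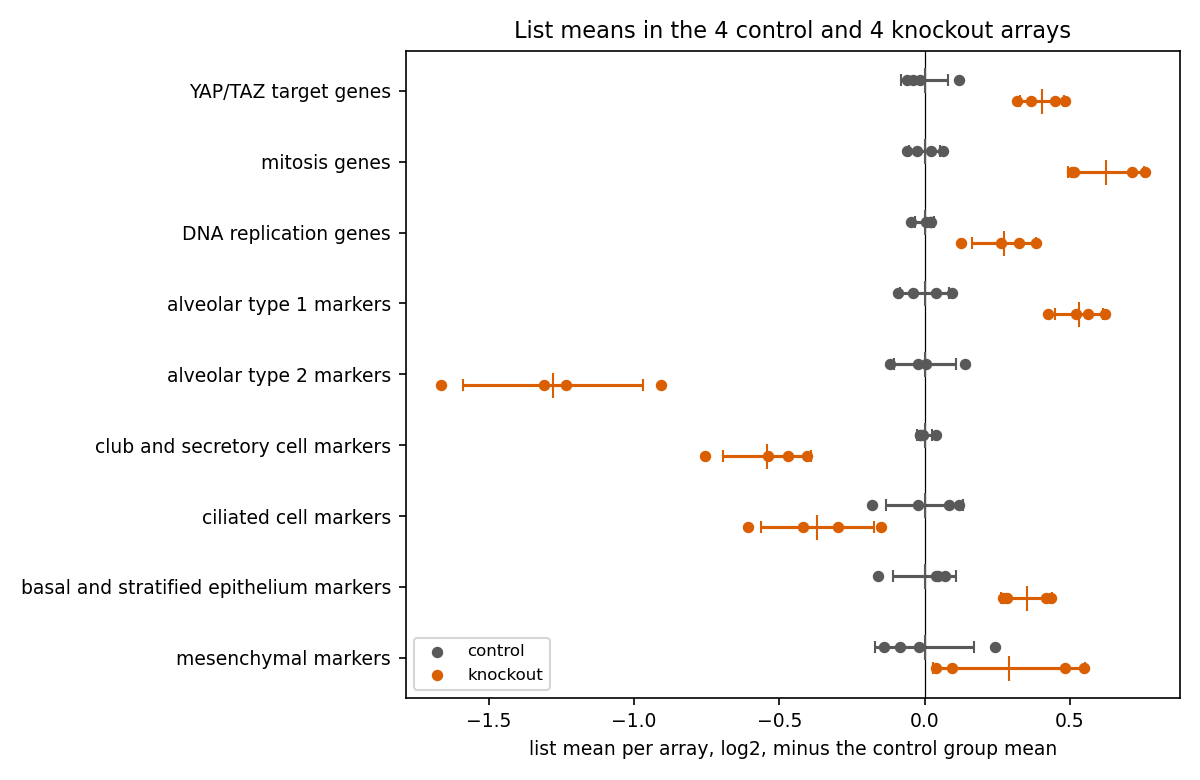
Each point is the mean of a list's members in 1 array, on the log2 scale and minus the mean of the control group, with bars for the group mean ± SD over 4 arrays. Between the groups the type 2 mean differed by −1.28 and the mitosis mean by 0.62, and the ciliated and mesenchymal means overlapped between the groups.

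Distal tip progenitor genes did not move together. Of 14 members 4 fell, 1 rose and 9 did not pass, and adjusted over the list alone 4 fell and 2 rose. Sox9, a transcription factor of the distal lung bud, fell 2.45-fold (−1.30, SE 0.12, adjusted p = 3.93e-05), as did Etv5 (−1.35, SE 0.14), Cpm (−0.82, SE 0.10) and Id2 (−0.60, SE 0.13), while Mycn rose (0.67, SE 0.064). These 4 other genes were named after their values were seen. Etv5 is also in the type 2 list, of which 20 of 22 members fell. The list median was 0.07 while its mean was −0.18 and camera's direction was down (adjusted p = 0.855), and over the alternatives the median lay between −0.0090 (mesenchymal marker mean as a covariate) and 0.11 (without control replicate 4). In the general epithelial list 3 of 20 genes rose, 3 fell and 14 did not pass, with the same counts adjusted over the list alone. There the transcription factor Elf3 fell 1.65-fold (−0.72, SE 0.094, adjusted p = 3.34e-04). Epcam itself, on which the cells were selected, did not pass (0.01, SE 0.097, adjusted p = 0.949). That list's median was −0.0054, with a sign that turned under several alternatives (at most to 0.07), its mean 0.01 and camera's direction up (adjusted p = 0.616), and without control replicate 4 the number of risen members was 5.

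Of the signalling lists, Wnt pathway genes had 4 members that fell, 1 that rose and 6 that did not pass out of 11, and adjusted over the list alone 4 fell and 2 rose (camera adjusted p = 0.251, median −0.03). The Wnt list passed with the mesenchymal marker mean as a covariate (median −0.14, camera adjusted p = 0.0345), and over the alternatives its median reached 0.02 (without control replicate 1). Sp5, a direct Wnt target, fell 1.64-fold (−0.72, SE 0.059, adjusted p = 2.24e-05), and the members that also fell were the feedback regulators Nkd1 (−0.88, SE 0.12) and Znrf3 (−0.37, SE 0.076) and the receptor Lgr5 (−0.92, SE 0.12). The ligand Wnt7b rose (0.59, SE 0.083), and Axin2 did not pass (−0.09, SE 0.059, adjusted p = 0.348). Of 13 Notch pathway genes 3 rose, 0 fell and 10 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.103, median 0.04), and the ligand Jag2 rose 1.32-fold (0.40, SE 0.058, adjusted p = 7.01e-04). The Notch median lay between −0.02 (mesenchymal covariate, where 1 member rose) and 0.07 (without knockout replicate 1). Of 11 p53 targets and cell cycle inhibitors 3 rose, 2 fell and 6 did not pass, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.121, median 0.10, or 0.05 with the mesenchymal covariate). Phlda3, a p53 target that restrains Akt, rose 1.60-fold (0.68, SE 0.069, adjusted p = 7.75e-05), as did Cdkn2b and Cdkn1b, while Sesn2 and Trp53inp1 fell. Of 11 neuroendocrine markers 2 fell, 1 rose and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.285, median −0.10, or −0.07 without control replicate 1, −0.06 without knockout replicate 2 and 0.24 in the 2 members above the median level), and the prohormone convertase Pcsk1 fell 1.49-fold (−0.58, SE 0.11, adjusted p = 0.00310). Only 1 neuroendocrine marker fell without control replicate 2, control replicate 3, knockout replicate 1 or knockout replicate 2. Members of these lists other than Sp5, Jag2, Phlda3 and Pcsk1 were named after their values were seen. By fry, the Wnt (adjusted p = 0.0109), p53 (adjusted p = 0.0137) and neuroendocrine (adjusted p = 0.0175) lists passed, whereas the Notch (adjusted p = 0.0574) and distal tip (adjusted p = 0.199) lists did not. The 8 primary lists all passed fry, with adjusted p from 4.58e-04 to 0.0206, while 0 of the 22 lists passed camera with an estimated correlation, where the lowest adjusted p was 0.147.

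Immediate early genes, which respond to tissue dissociation, were lower in the knockout cells. Of 15 measured members 12 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. Socs3, a feedback inhibitor of cytokine signalling, fell 1.73-fold (−0.79, SE 0.064, adjusted p = 2.16e-05), and the transcription factors Jun (−0.44, SE 0.079) and Fos (−0.27, SE 0.069) fell less, while Ier3 rose (0.65, SE 0.089). Jun, Fos and Ier3 were named after their values were seen. The list median was −0.36 (camera adjusted p = 2.58e-05, adjusted p = 0.161 with an estimated correlation).

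Markers of cell types that the Epcam selection should remove were measured as well. Of 14 endothelial markers 5 rose, 0 fell and 9 did not pass, and adjusted over the list alone 10 rose and 0 fell (median 0.27, camera adjusted p = 9.22e-05, adjusted p = 0.242 with an estimated correlation). Tek, the angiopoietin receptor, rose 1.37-fold (0.45, SE 0.088, adjusted p = 0.00456), and without control replicate 4 the number of risen endothelial markers was 8. With the mesenchymal marker mean as a covariate 3 endothelial markers rose and the median was 0.15 (camera adjusted p = 0.00157). Of 7 mesothelial markers 2 rose, 0 fell and 5 did not pass, with the same counts adjusted over the list alone (median 0.25, camera adjusted p = 0.00212, adjusted p = 0.242 with an estimated correlation). Those that rose were Msln, mesothelin, 1.68-fold (0.75, SE 0.065, adjusted p = 3.15e-05), and Upk1b, a uroplakin (1.43, SE 0.17), the latter named after its value was seen. The mesothelial median depended on single arrays, at 0.14 and 0.44 without control replicates 1 and 4 and 0.43 and 0.16 without knockout replicates 1 and 4, and was 0.47 among genes above the median level, where 5 members are left. With the mesenchymal covariate the mesothelial list lost its call and its median turned to −0.05 (camera adjusted p = 0.153), while 2 members still rose. Of 10 erythroid markers 1 rose, 0 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.07, camera adjusted p = 0.183), while over the alternatives that left any member the median lay between −0.02 (mesenchymal covariate) and 0.12 (without knockout replicate 2). That gene was Epor, the erythropoietin receptor (0.33, SE 0.067, adjusted p = 0.00556). In the control arrays 13 of the 14 endothelial, 4 of the 7 mesothelial and 0 of the 10 erythroid markers lay above the median of all genes.

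Of 20 mesenchymal markers 2 rose, 0 fell and 18 did not pass, and adjusted over the list alone 0 rose and 0 fell. The list median was 0.37, with camera adjusted p = 4.80e-04, adjusted p = 0.425 with an estimated correlation and fry adjusted p = 0.173. The receptor Pdgfrb rose 1.48-fold (0.57, SE 0.16, adjusted p = 0.0297), as did Col1a2 (0.49, SE 0.14, adjusted p = 0.0369), the latter named after its value was seen. The number of risen mesenchymal markers was 0 without control replicate 1, 2 or 3 or knockout replicate 3 or 4, 5 without control replicate 4 and 8 without knockout replicate 1, and it was 0 with array weights, where the median was 0.24. With its own mean as a covariate the list by construction lost its call (median 0.01, camera adjusted p = 0.678). Pdgfrb lost its call without control replicate 1, 2 or 3 or knockout replicate 2, 3 or 4, with adjusted p from 0.0507 to 0.0899. In the control arrays 14 of the 20 mesenchymal and 12 of the 15 leukocyte markers lay above the median of all genes.

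Of 15 leukocyte markers 1 rose, 0 fell and 14 did not pass, and adjusted over the list alone 0 rose and 0 fell (median 0.18, camera adjusted p = 0.0925). That gene was Itgam, an integrin of myeloid cells (0.56, SE 0.17, adjusted p = 0.0386), which lost its call without any 1 of control replicates 1, 3 and 4 or knockout replicates 2, 3 and 4. The leukocyte list passed without control replicate 2 (4 risen members, camera adjusted p = 2.60e-04, median 0.41) and without knockout replicate 1 (camera adjusted p = 0.0390, median 0.27), as it did with Xist as a covariate (camera adjusted p = 0.0140, median 0.28), an alternative added after the data were seen. The median was 0.05 without control replicate 1 (camera adjusted p = 0.847), 0.09 without knockout replicate 4 and 0.07 with the mesenchymal covariate.

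The arrays differed in sex-linked transcripts within both groups. Xist, the RNA of the inactive X chromosome, was 12.30, 5.85, 12.32 and 5.90 in control replicates 1 to 4 and 10.31, 12.36, 12.43 and 6.33 in knockout replicates 1 to 4 (difference 1.26, SE 1.77, adjusted p = 0.717). The Y-linked Eif2s3y, named after its values were seen, was at 9.52, 9.64, 9.57 and 9.31 in control replicates 2 and 4 and knockout replicates 1 and 4, and between 4.16 and 4.40 in the other arrays. Knockout replicate 1 alone was high in both. Ddx3y was not analysed here. With knockout replicates 1 and 4 left out, the latter being the array farthest from the rest of its group on principal component 2, 2903 genes changed. With the mesenchymal marker mean as a covariate 2278 genes changed, with 1041 genes higher in knockout and 1237 genes lower in knockout. Both alternatives were added after the data were seen.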

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

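The tests of the type 1 and type 2 markers, of the Dlk1 to Dio3 interval and of sex-linked genes and Stk4 in knockout replicate 1 were chosen only after the result was seen.

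Among the 35 splits of the 8 arrays into 4 and 4, only the real one gave as many as 3746 changed genes. The highest other split gave 3 and set control replicates 1 and 3 with knockout replicates 2 and 3, the arrays with the highest Xist. All other splits mix knockout with control arrays, so a group difference widens their spread and lowers their counts. With 35 splits the smallest share possible is 1 of 35, which makes chance in the grouping less likely but does not exclude it. A litter or batch that follows the groups would not be seen by these splits.

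In 11 of 148 groups of 4 arrays a single array lay far from the other 3, and chance gives about 1 in 20 groups. Knockout replicate 1 was above the other knockout arrays in Pon1 (8.46, the others from 5.56 to 5.93), Gdpd2 (8.50, the others from 6.84 to 7.11) and C6 (7.63, the others from 6.19 to 6.41). Control replicate 2 was above the other control arrays in Stk4 (9.84), Pon1 (11.54) and C6 (10.07) and below them in the mean of the basal and stratified epithelium list (7.25, the others from 7.45 to 7.48). Control replicate 4 was above the other control arrays in Mcm3 (7.04) and in the mean of the immediate early genes (11.39). Ajuba was lower in knockout replicate 3 (9.86) than in the other knockout arrays, and Msln was lower in knockout replicate 4 (12.52, the others at 12.60).

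Among the 12146 probe sets with no symbol given, which the comparison of genes leaves out, 873 changed when every probe set was tested on its own, 596 higher and 277 lower in knockout cells, while those with 1 symbol gave 1544 higher and 1761 lower.

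In the genes that fell most and in sex-linked genes, knockout replicate 1 stood apart from the other knockout arrays. Over 50 genes that fell at least 4-fold in the other 3 knockout arrays, the share of control level that would have to be mixed into it had a median of 15.4% (quartiles 13% and 18.2%) and was above 0 in all 50. The same estimate for knockout replicates 2, 3 and 4, each over its own genes chosen in that way (38, 36 and 32), gave medians of −1.65%, −2.52% and −7.22%. Their reference includes knockout replicate 1, which by construction pulls these medians down. RNA of control-type cells is a candidate explanation from the genes that fell. Genes that rose did not set the array apart, at 8.45% (quartiles −9.93% and 29.8%) against 12.2%, 0.811% and 13% in knockout replicates 2, 3 and 4. Such a mixture would give a like share in the genes that rose, and their wide quartiles do not decide it. Its Xist was 23.3% of the level in the 4 arrays that have it, while Eif2s3y, Kdm5d and Uty were at 106%, 121% and 89.6% of theirs. Signal of both kinds was present, so RNA from cells of both sexes is a candidate. Such a mixture would also lower the Y-linked genes, which was not seen in Eif2s3y or Kdm5d. The other arrays that have them ranged from 9.31 to 9.64 in Eif2s3y and from 7.92 to 8.23 in Kdm5d. A small lowering could not be seen against that spread, so these genes do not decide it. Less complete deletion cannot be told apart from RNA of control-type cells by the genes that fell. Alone it would not give Xist beside Y-linked signal in the same array, but it could occur together with RNA of both sexes. Stk4 was only 0.12 above the mean of the other 3 knockout arrays, whose SD was 0.10, and its probe set may lie outside the deleted exons. A milder response of the animals behind this array, the biological alternative, was not tested. By array weight and principal component 2, knockout replicate 4 lay farthest from its group. Its weight was 0.325, against 1.66 in knockout replicate 1. On component 2 it was at 21.1, against −11.7, −8.97 and −5.29 in knockout replicates 1 to 3. Knockout replicates 2 to 4 share the pull of the reference, so that pull does not account for the lower share in knockout replicate 4.

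Type 1 markers rose while type 2 markers fell. If fewer type 2 cells alone raised every other epithelial type alike, club and ciliated markers would have risen too, but their medians were −0.46 and −0.30. If more RNA of non-epithelial cells diluted the epithelial RNA, the general epithelial genes would have fallen by about the type 2 median of −1.13, but their median was −0.0054 and the lowest of the 20 lay at −0.72. A change in the share or in the state of the type 1 and type 2 cells themselves remains a hypothesis, and arrays of whole cell populations do not separate share from state.

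Genes of the imprinted interval from Dlk1 to Dio3 fell together, 46 of 48 measured with 0 risen (median −1.30, from −2.42 for Mir369 to −0.12 for Mir666), all named after their values were seen. The mean of its 40 microRNA genes was 8.30, 8.20, 8.31 and 8.40 in control and 7.16, 6.88, 6.78 and 6.64 in knockout arrays, and many of them lie in shared host transcripts and are not independent. Against a lower signal of microRNA probe sets in general stands the median of −0.012 over 260 microRNA genes elsewhere, and against a lower recovery of small RNAs stand the median of 0.36 over 51 small nucleolar RNA genes named Snora or Snord, all of them elsewhere, and the falls of the long transcripts Rian (−1.18, SE 0.079), Dlk1 (−0.75, SE 0.077), Meg3 (−0.68, SE 0.061) and Rtl1 (−0.48, SE 0.061). Lower transcription of the interval in the knockout epithelium may therefore be biological, as a hypothesis, while a smaller share of a cell type that expresses it was not tested.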

How the results depend on the processing

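The alternatives that leave out knockout replicates 1 and 4 together or add a covariate were chosen only after the result was seen. Of the counts of changed genes, 54 stayed within 1.5 times the reported value and 9 did not, namely 2278 genes changed between knockout and control (1041 genes higher in knockout, 1237 genes lower in knockout) with the mesenchymal marker mean as a covariate, 1030 (383 and 647) at a minimum of 1.5-fold and 1030 (393 and 637) by treat against 1.2-fold. The last 2 ask for a larger change by construction, and for the covariate the cause was not tested. Leaving out each array in turn gave 2766 (without knockout replicate 3) to 3978 (without knockout replicate 4) changed genes. With single arrays left out Stk4 ranged from −0.33 (without knockout replicate 1) to −0.24 (without control replicate 2), and over all alternatives it lost its call without knockout replicate 3 (−0.28, adjusted p = 0.0592), with knockout replicates 1 and 4 left out (−0.29, adjusted p = 0.0703) and with the mesenchymal covariate (−0.21, adjusted p = 0.178), over all its alternatives the adjusted p lying between 0.0123 and 0.178. For the first 2 of these fewer arrays were used, and for the covariate the cause was not tested. The 8 primary lists kept their call in 152 combinations of list and alternative, and lost it only in camera with an estimated correlation, where the medians by construction stay at 0.40 (YAP/TAZ), 0.63 (mitosis), 0.32 (DNA replication), 0.40 (type 1), −1.13 (type 2), −0.46 (club), −0.30 (ciliated) and 0.15 (basal). Camera's direction reversed for distal tip genes under quantile normalization (median 0.068) and without control replicate 1 (0.060, within a range from 0.015 without knockout replicate 3 to 0.11 without control replicate 4), and the median of neuroendocrine markers became 0.24 among genes above the median level, where fewer members were left. None of these passed the test under either setting. Counting each gene or list under each alternative, 905 values of named genes stayed on their side of the threshold and 20 lost their call, and for the secondary lists 259 stayed, 9 lost the call and 8 gained it. Across genes the replicate numbers gave no sign of pairing the arrays. The correlations of same-numbered deviations were 0.06, 0.10, −0.08 and 0.04, and only 1 knockout array correlated best with its own number. Pairing in some genes is not excluded. The mesenchymal marker mean rose with the number in both groups. It was 8.02, 8.08, 8.14 and 8.41 in control replicates 1 to 4 and 8.20, 8.26, 8.65 and 8.71 in knockout replicates 1 to 4. The replicate block gave 3494 changed genes, 3242 of them among the reported ones, with 11 instead of 2 risen mesenchymal markers (camera adjusted p = 6.36e-07) and a leukocyte list that passed (camera adjusted p = 0.0408). Dim genes limit what can be seen, and 3076 of the 9969 genes above the median level changed.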

Other observations

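The gene families below were chosen after the data were seen, as were the tests of them, and members of a family are not independent. Fisher's exact test compared each of 12 families with all other genes, separately for rises and falls, with adjustment over both directions of all families. Semaphorins, secreted or membrane-bound guidance molecules, held 9 genes that rose and 3 that fell among 20 (adjusted p = 1.06e-04 for rises). Those that rose most were Sema3e (1.04, SE 0.10), Sema3b (1.03, SE 0.10) and Sema5a (0.91, SE 0.095), while Sema4f (−1.36, SE 0.15), Sema4a (−0.78, SE 0.11) and Sema4g (−0.51, SE 0.078) fell. Of 12 annexins, which bind membrane phospholipids in the presence of calcium, 6 rose and 0 fell (adjusted p = 0.00113), led by Anxa1 (0.92, SE 0.082), Anxa8 (0.85, SE 0.13) and Anxa5 (0.85, SE 0.14). Of 6 uroplakins, membrane proteins first known from urothelium, 3 rose and 0 fell (adjusted p = 0.0250), namely Upk1b (1.43, SE 0.17), Upk1a (1.26, SE 0.17) and Upk3bl (1.23, SE 0.098), and 1 fell after median centring or quantile normalization. Upk1b is also a mesothelial marker, and the mean of that list was 0.49 higher in the knockout group. Of 52 keratins 10 rose and 1 fell (adjusted p = 0.0264), and of 44 collagens 10 rose and 3 fell (adjusted p = 0.0123). The collagens that rose include the basement membrane chains Col4a1 (0.71, SE 0.071), Col4a2 (0.67, SE 0.065), Col4a3 (0.65, SE 0.082) and Col4a4 (0.73, SE 0.080), in arrays whose mesenchymal marker mean was also 0.29 higher in the knockout group. Col4a3 and Sema3e are also in the type 1 list, of which 16 of 20 members rose. Among the risen keratins, Krt4, Krt13, Krt14 and Krt15 are in the basal list and Krt7, Krt8 and Krt19 in the general epithelial list.

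Small nucleolar RNA genes named Snora or Snord, most of which guide the modification of ribosomal RNA, rose in 22 of 51 and fell in 0 (adjusted p = 1.03e-09), for example Snord47 (1.01, SE 0.19) and Snord15b (0.92, SE 0.17), while the 3 small nucleolar RNA genes measured from Dlk1 to Dio3, which have other names, all fell. Histone genes rose in 14 of 44 and fell in 1 (adjusted p = 8.93e-05), numbers that were 10 and 2 under quantile normalization. Kinesins rose in 13 of 37 and fell in 1 (adjusted p = 8.04e-05), or 2 under median centring or quantile normalization, with Kif11, Kif23 and Kif20a also in the mitosis list. Solute carriers fell in 52 of 358 (adjusted p = 0.0228), among them Slc22a19 (−2.33, SE 0.22), Slc24a4 (−1.95, SE 0.14) and Slc26a9 (−1.80, SE 0.16), and rose in 20. Serpins (6 rose and 2 fell of 47) and interferon-induced genes (3 rose and 3 fell of 38) did not pass in either direction. Ribosomal protein genes fell in 0 of 57, fewer than among other genes (adjusted p = 0.0123), and rose in 4, or 2 under median centring and 3 under quantile normalization. Except where stated, the counts moved by at most 6 under median centring or quantile normalization, and the sign of each family median stayed the same.

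Of 9 genes with a mean log2 value of at least 13, Sftpc among them, 1 rose and 0 fell, and the largest absolute difference was 0.20. The cut uses the mean over both groups, so a gene that is bright in control and falls can drop out. Cxcl15, for example, was at 13.21 in control and changed by −0.96. These counts therefore do not show that the genes brightest in control were unchanged.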
